A study of Oryza sativa with 20 samples.

How the data were processed

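RNA from 20 libraries of rice shoots, 10 groups of 2 biological replicates, was sequenced on an Illumina instrument after extraction with a plant RNA kit, per the labels' protocols. The submitters' processing notes name cutadapt, TopHat2 and Cufflinks, with no version given in the sources used here, and the genome build IRGSP-1.0. The expression values are FPKM as deposited, with 1 column per group, so the authors combined the replicates before the table was made. For each time the table also holds a log2 fold change and a q-value computed by the authors, per the file headers; the test behind the q-value is not given in the sources used here, and the deposited q-values carry 2 decimals. Samples were grouped by their labels, which give the bath temperature and the time of sampling. No column of other samples was used.

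The table has 48683 rows under 37248 gene IDs, of which 8490 occur on more than 1 row. Rows with identical values in every column were taken as 1 record, and 3381 rows at 0 in all 10 groups were left out, which gave 42692 records. In 106 records the deposited log2 fold change departed by more than 0.1 from the ratio of the deposited FPKM values at a time where both were at least 1 FPKM, and these were left out. A mean of at least 1 FPKM over the 10 groups left 24219 records. A value of exactly 0 can be a failed estimate: 12 compared records had a median of at least 10 FPKM and were listed at 0 in a group. No single ratio against 0 is given without the pseudocount. Counts of calls of at least 2-fold or 10-fold, and of records induced at least 20-fold at 1 h, used FPKM without a pseudocount. A record at 0 in 1 of the compared groups can therefore enter these counts. Where reads could belong to overlapping or near-identical genes, the authors' assignment was kept, and whether strand was used is not given in the sources used here.

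The planned analysis was a limma model over the 20 libraries with gene set tests by camera. It was not run, because the table gives no value per library, and no p-value was computed here. Calls were instead taken from the authors' q-values in the deposited table at a threshold of 0.05, with the direction from the FPKM values. A printed q of 0.0 stands for a value that rounds to 0 at 2 decimals. Log2 ratios were computed on log2(FPKM + 1). The smallest ratio called, taken from the FPKM values without a pseudocount, was 1.55-fold to 1.60-fold, depending on the time. Depth per library is unknown, and the FPKM values give no interval or floor. Differences between adjacent times and between control groups were described by a log2 difference of at least 1. Shared calls were set beside the product of both counts over the 24219 records. No control group served at more than 1 time.

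Gene lists had been fixed before the data were examined, 43 in all. The reference table of gene names at hand (assembly ASM3414082v1) matched 0 of the gene IDs and the files do not pair IDs with names, so 38 lists that needed descriptions, among them markers of other tissues, were not formed. The remaining 5 lists, small heat shock proteins (16 IDs), HSP70 (8), HSP90 (5), HSP100 and Clp ATPases (3) and heat stress transcription factors (23), had IDs written down beforehand from background knowledge. These IDs were not checked against an annotation. Of the list members 15, 8, 4, 3 and 19 records passed the filter, and 3 of the transcription factor records carry more than 1 gene ID. Each list's median log2 ratio was placed among 10000 random lists of the same size, matched on 10 classes of mean expression. This mean was taken over all 10 groups, heated ones included, so the lists were not matched on the level in controls. On simulated log2 ratios for the 24219 records, with lists of the sizes above, 8 to 13 of 200 unchanged lists fell outside percentiles 2.5 to 97.5. The simulated ratios were independent between records and unrelated to expression, and the unchanged lists were drawn at random. The simulation therefore checks the calculation, and not how often lists of related genes would fall outside. Of 100 lists of records with a planted log2 shift of 1.5, 98 lay above this range at a size of 3 and 100 at each larger size; smaller shifts were not simulated.

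The rule for single genes, fixed beforehand, allowed at most 2 unnamed IDs per direction at each of the 5 times, those with the largest rise and fall among the calls. It was applied more narrowly than fixed, at 10 min only, and these 4 IDs were followed through the later times. The largest calls of later times are therefore not all named. The rule's condition on agreement between replicates could not be applied. Chromosome positions, GC content and transcript length were not analysed here, as no sequence of the build was used. Alternatives were a pseudocount of 0.1, no filter or a mean of at least 5 FPKM, rescaling each group by its median ratio to the geometric mean over 10135 records above 5 FPKM in every group, rows summed per gene ID, and a q of 0.01. Work was done in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.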

Results

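The series followed the transcriptome of wild-type rice (Oryza sativa) shoots through a short heat shock and the recovery from it. Pots of 2-week-old plants were turned upside down so that the shoots hung in water at 42 °C, or in water at 22 °C as the control, for 10 min. Shoots were taken at the end of the bath or after recovery at 30 °C, and sampling times are given here from the start of the bath, at 10 min, 20 min, 1 h, 2 h and 10 h. The recovery temperature lay between those of the 2 baths. A difference between heated and control shoots, called a heat effect here, therefore cannot be told apart from a response of the controls to 22 °C or to the later move to 30 °C. Each of the 10 groups held 2 libraries, and each library came from 3 shoots.

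Expression was given as FPKM (fragments scaled to transcript length and to the number of mapped fragments), with a single value per group made by the authors from both libraries. No SD or n of libraries can therefore stand beside a level, and no difference below has a replicate check of its own. A change is called here when the q value in the authors' deposited table was below 0.05, and its size is given as the log2 ratio of heated to control on the log2(FPKM + 1) scale, which understates the change of low values. Depth per library is unknown, since FPKM values carry no counts. The summed FPKM ran from 661049 in the 2 h controls to 1175514 in the shoots heated and sampled at 1 h, where the matching controls summed to 819654. A record is a distinct set of group values; 24219 records with a mean of at least 1 FPKM were compared, and 1570 of them carried more than 1 gene ID.

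The first comparison asked which transcripts had moved by the end of the 10 min bath. Small heat shock proteins, chaperones that hold unfolding proteins, made up the clearest group, with 11 of 15 tested members higher in the heated shoots in the authors' deposited table. Their median rose from 2.37 FPKM in the controls to 1362.76 FPKM. The other 4 members had log2 ratios of 7.60 to 11.13 but no printed q below 0.05. The highest of them was listed at 0 FPKM in the controls and at 2239.88 FPKM after heat, with q = 0.6 in the authors' deposited table. The lowest had a q printed as 0.05, which can be rounded from a smaller value. All 3 members of the list of HSP100 and Clp ATPases, the disaggregase family, were called higher in the authors' deposited table, as were 3 of 4 HSP90 and 4 of 8 HSP70 members. Among heat stress transcription factors, which bind the promoters of heat shock genes, 7 of 19 records rose and none fell in the authors' deposited table, and the largest rise went from 0.31 to 336.73 FPKM.

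Over all 24219 records, the lists included, 884 passed the threshold in the authors' deposited table, 362 higher and 522 lower after heat, and 323 of the rises and 372 of the falls were at least 2-fold. Among the called records the 2 largest rises were OS05G0519700, which stood on the list of HSP100 and Clp ATPases, from 1.19 to 2488.54 FPKM (log2 ratio 10.15), and OS03G0266900, on the list of small heat shock proteins, from 2.94 to 4125.81 FPKM (log2 ratio 10.03). The 2 largest falls among them were OS03G0108300, from 42.65 to 3.43 FPKM (log2 ratio -3.30), and OS03G0823400, from 26.15 to 3.0 FPKM (log2 ratio -2.76). Each of these 4 had a q printed as 0.0 in the authors' deposited table. The balance of rises and falls depended on the filter: with no filter on low values the authors' deposited table called 1423 records at 10 min, 882 higher and 541 lower. Of these, 350 higher and 1 lower were low records that are taken up further below as secondary records.

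**Figure D1:**
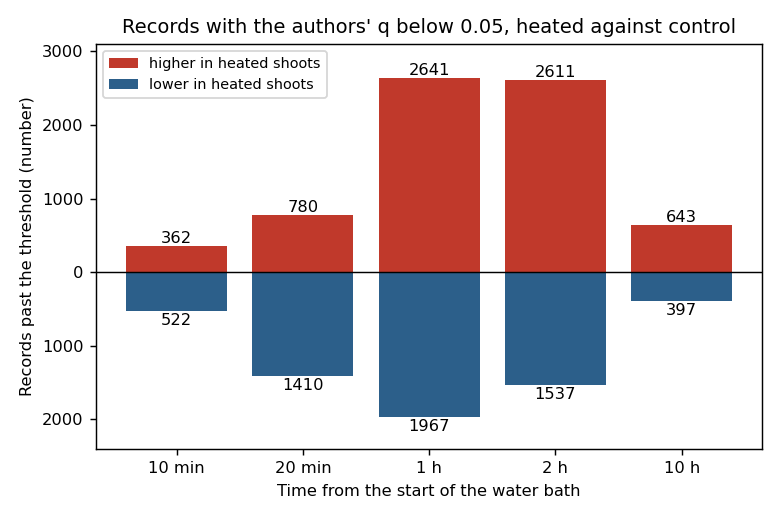
Number of records (vertical axis) past the threshold of 0.05 on the q value of the authors' deposited table at each time from the start of the bath (horizontal axis, not to scale), with records higher in heated shoots above the zero line and records lower in heated shoots below it. Rises went from 362 at 10 min to 2641 at 1 h and stood at 643 at 10 h, and falls were most numerous at 1 h, with 1967.

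At 20 min, after 10 min of recovery, falls outnumbered rises among the records compared. The authors' deposited table called 2190 records, 780 higher and 1410 lower, with 608 rises and 1110 falls of at least 2-fold. With no filter on low values these calls were nearly even in the authors' deposited table, 1440 higher and 1472 lower. In heated shoots the median FPKM of each chaperone list was higher than at 10 min, a difference that was not tested. The median of the small heat shock proteins was 2350.78 FPKM in heated shoots against 1.67 FPKM in controls, with 10 of 15 members called in the authors' deposited table. All 4 HSP90 members and 5 of 8 HSP70 members were now called higher in the authors' deposited table. OS05G0519700 reached 5415.61 FPKM against 1.02 FPKM and OS03G0266900 reached 7284.46 FPKM against 2.46 FPKM, again the 2 largest rises among the calls. Of the 1410 falls, 309 were in records at least 2-fold higher in the 20 min controls than in the 10 min controls, a count raised by its own construction because the 20 min controls enter both comparisons.

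The heat effect was widest at 1 h. The authors' deposited table called 4608 records, or 19.0% of those compared, 2641 higher and 1967 lower, and 549 of the rises were at least 10-fold. The 5 chaperone and transcription factor lists together took 17.1% of all FPKM in the heated shoots at this time, against 0.162% in the matching controls. Small heat shock proteins alone took 10.3%, and their highest member, OS03G0266900, reached 20881.9 FPKM against 8.42 FPKM. HSP70 members ranged from a log2 ratio of -0.08 to one of 10.24, with 6 of 8 called higher in the authors' deposited table; the least moved stood at 74.16 FPKM after heat and 78.35 FPKM in the controls (q = 0.92). Among heat stress transcription factors 13 of 19 records were called higher and none lower in the authors' deposited table, and the highest reached 2344.69 FPKM against 12.28 FPKM. OS03G0108300, the largest called fall at 10 min, was not called at 20 min, at 4.23 against 10.53 FPKM (q = 0.15 in the authors' deposited table), where its control value was also lower than at 10 min. At 1 h it was again the largest called fall, at 1.85 against 48.53 FPKM (log2 ratio -4.12, q printed as 0.0 in the authors' deposited table).

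**Figure D2:**
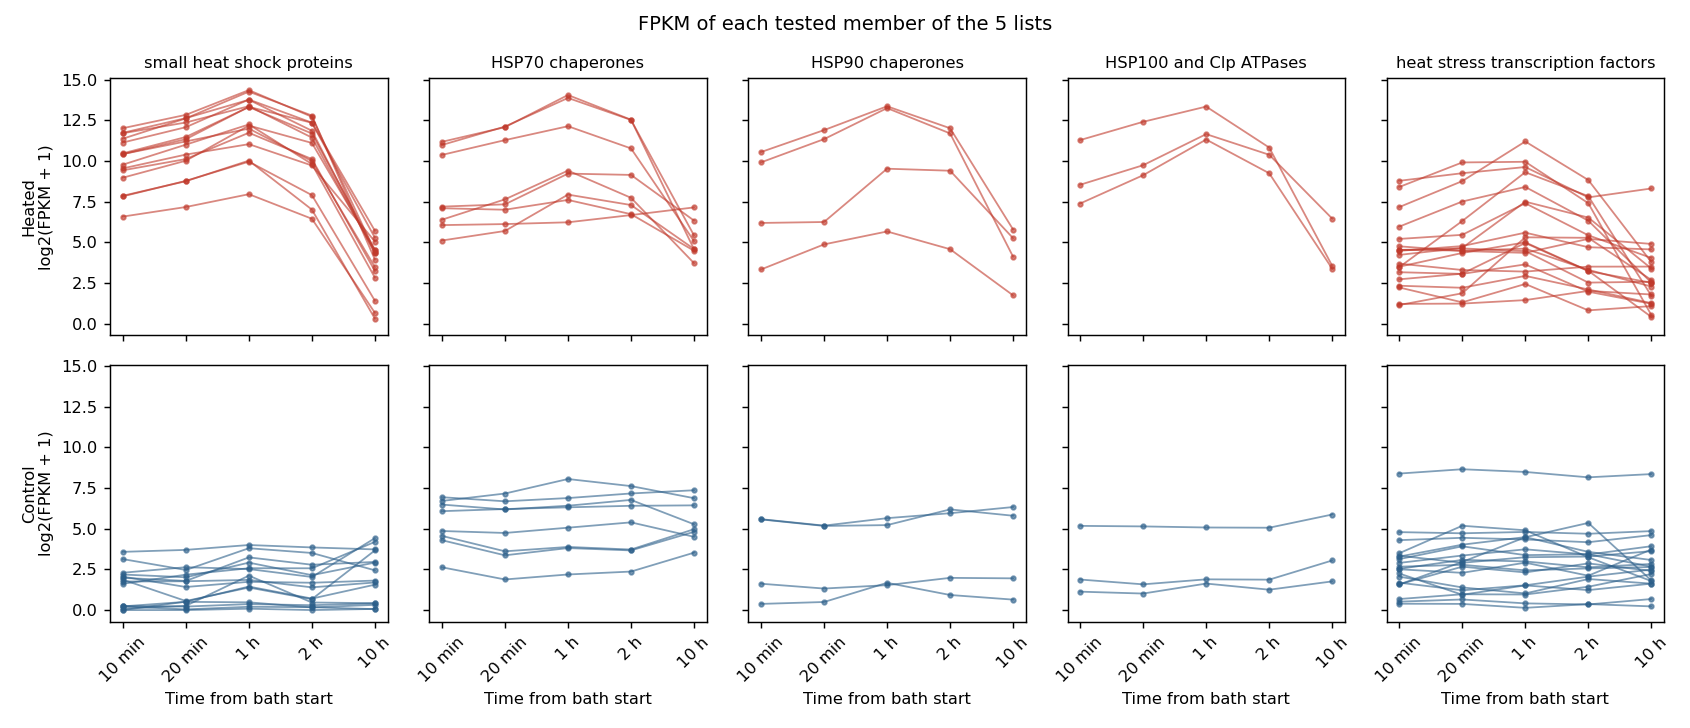
Expression of each tested member of the 5 lists as log2(FPKM + 1) (vertical axis) at the 5 times from the start of the bath (horizontal axis, not to scale), with heated shoots in the upper row and control shoots in the lower row. Each line is one record and each point the authors' value for a group; lines of the small heat shock proteins are highest at 1 h, up to 20881.9 FPKM, and lie at 51.32 FPKM or lower at 10 h.

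By 2 h the number of rises among the records compared had hardly moved, while the median FPKM of each chaperone list in heated shoots was lower than at 1 h. Neither was tested as a difference. With no filter on low values the rises in the authors' deposited table went from 3461 at 1 h to 2869 at 2 h. Calls in the authors' deposited table numbered 4148, 2611 higher and 1537 lower. The 5 lists took 8.91% of all FPKM, and the median of the small heat shock proteins was 2201.14 FPKM after heat against 1.63 FPKM in controls. All 3 HSP100 and Clp members, 3 of 4 HSP90 members and 4 of 8 HSP70 members were called higher in the authors' deposited table. The uncalled HSP90 member still stood at 4118.74 against 60.75 FPKM (q = 0.11 in the authors' deposited table). The log2 ratios of the uncalled HSP70 members ran from -0.03 to 8.87. The highest of these stood at 5924.38 against 11.68 FPKM (q = 0.21 in the authors' deposited table). Heat stress transcription factors called higher in the authors' deposited table went from 13 at 1 h to 7 at 2 h, a difference that was not tested. OS03G0823400, which fell at 10 and 20 min, was higher after heat at 1 h (44.36 against 20.24 FPKM) and at 2 h (110.82 against 16.08 FPKM), each with q printed as 0.0 in the authors' deposited table.

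At 10 h most of the response had gone. The authors' deposited table called 1040 records, 643 higher and 397 lower, and only 324 of the rises and 294 of the falls were at least 2-fold; 11 rises were at least 10-fold, against 549 at 1 h. Small heat shock proteins had a median of 18.93 FPKM against 2.51 FPKM, and 4 of 15 members were still called higher in the authors' deposited table. No HSP70 member was called higher and 1 was called lower, from 116.16 to 41.96 FPKM (q printed as 0.0 in the authors' deposited table). Of the 4 HSP90 members 1 was still called higher, at 16.31 against 0.56 FPKM (q printed as 0.0 in the authors' deposited table). OS03G0108300 was no longer called, at 45.03 against 45.11 FPKM (q = 1.0 in the authors' deposited table). No heat stress transcription factor was called in either direction in the authors' deposited table. OS05G0519700 remained at 10.77 against 2.39 FPKM, OS03G0266900 at 20.45 against 6.76 FPKM and OS03G0823400 at 157.12 against 41.47 FPKM, each with q printed as 0.0 in the authors' deposited table.

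Set against random lists of the same size and class of mean expression, the median log2 ratio of each of the 5 lists lay at or above percentile 99.7 at 10 min, 20 min, 1 h and 2 h. The mean was taken over all 10 groups, so heated values helped set the class and the matching was not on the control level. Some small heat shock protein members, below 1 FPKM in the controls at every time, passed the filter only through their heated values. For the small heat shock proteins the median log2 ratio was 8.13 at 10 min, 9.30 at 20 min, 10.46 at 1 h, 9.14 at 2 h and 1.40 at 10 h, at percentile 100 each time. At 10 h the HSP100 and Clp list lay at percentile 90.3, HSP70 at 16, heat stress transcription factors at 6.8 and HSP90 at 3.4. These percentiles describe the deposited group values and are not tests, and membership of the lists came from background knowledge, not from an annotation of these IDs.

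The next comparison asked whether records moved by heat at one time were those moved at the next. Of the 362 records called higher at 10 min in the authors' deposited table, 248 were also called higher at 20 min, where independent lists would share 11.7, and 303 were called higher at 1 h against 39.5. Falls shared by 10 and 20 min numbered 311 against 30.4 in the authors' deposited table. From 20 min to 1 h, 471 rises were shared against 85.1 and 450 of the 1410 falls against 114.5, and 233 records fell and then rose against 153.8, by the calls of the authors' deposited table. Between 1 h and 2 h, 1610 rises and 675 falls were shared in the authors' deposited table, against 284.7 and 124.8 for independent lists. Between 2 h and 10 h, 150 rises were shared against 69.3, and 199 falls against 25.2, by the calls of the authors' deposited table. The independent values take no account of abundance. Across records, which are not independent replicates, log2 ratios at adjacent times had Pearson's r of 0.66 from 10 to 20 min, 0.53 from 20 min to 1 h, 0.72 from 1 to 2 h and 0.14 from 2 to 10 h.

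Calls also turned over in direction. In all, 358 records fell at 20 min and rose at 1 h or 2 h in the authors' deposited table, and 32 did the opposite. In the 358, the median in heated shoots was 6.62 FPKM at 10 min, 6.55 FPKM at 20 min and 23.05 FPKM at 1 h, and the median in controls was 8.84, 17.89 and 10.88 FPKM; choosing records by their fall at 20 min favours high control values at that time. A further 1097 records were called higher at both 1 h and 2 h with no call at 10 or 20 min in the authors' deposited table; their median log2 ratio was 0.07 at 10 min, 0.08 at 20 min, 1.70 at 1 h, 1.57 at 2 h and 0.02 at 10 h. Only 179 records were called higher at each of 10 min, 20 min, 1 h and 2 h in the authors' deposited table, with a median of 304.68 FPKM against 7.26 FPKM at 1 h and of 8.90 FPKM against 7.37 FPKM at 10 h. Another 79 were called lower at the same 4 times in the authors' deposited table, with a median log2 ratio of -1.78 at 1 h and -0.19 at 10 h.

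**Figure D3:**
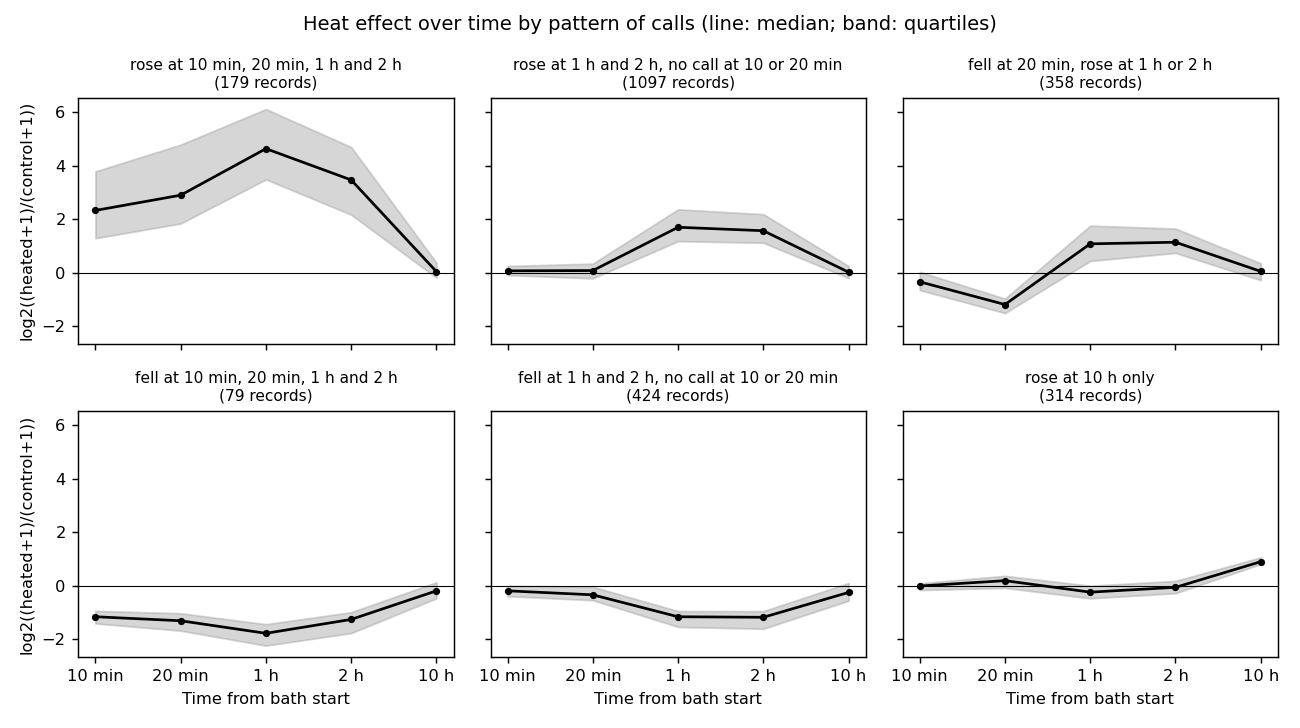
Log2 ratio of heated to control shoots on the log2(FPKM + 1) scale (vertical axis) at the 5 times from the start of the bath (horizontal axis, not to scale) for 6 patterns of calls in the authors' deposited table. Lines are medians over records and grey bands the quartiles; the 179 records called higher at the first 4 times have a median of 4.64 at 1 h and 0.04 at 10 h, and the 314 called higher at 10 h alone a median of 0.90 there. Records were placed in a panel by these same calls, so the direction at the called times is fixed by the choice.

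How far the heat effect itself shifted between adjacent times could be described but not tested without values per library. Among records called at either time in the authors' deposited table, the log2 ratio differed by 1 or more in 774 of 2503 from 10 to 20 min, in 3077 of 5630 from 20 min to 1 h, in 2114 of 6427 from 1 to 2 h and in 2876 of 4758 from 2 to 10 h. From 20 min to 1 h the later ratio was the higher one in 2318 records and the lower one in 759. From 2 to 10 h it was the higher one in 975 and the lower one in 1901.

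The controls, which were also inverted and immersed, differed between times as well. The 10 min controls were taken from the 22 °C bath and all later controls after recovery at 30 °C. Counts against the 10 min controls therefore mix time with this change of temperature. Against the 10 min controls, 864 records were at least 2-fold higher and 514 at least 2-fold lower at 20 min. The corresponding numbers were 908 and 1099 at 1 h, 649 and 990 at 2 h, and 1472 and 1680 at 10 h. In all, 5621 records differed by at least 2-fold at 1 or more later times. The number was 3382 when a mean of at least 5 FPKM was required, 8184 with a pseudocount of 0.1 and 4849 with rows summed per gene ID. These counts rest on group values with no test. By Pearson's r across records on the log2(FPKM + 1) scale, heated and control shoots were at 0.927 at 10 min, 0.892 at 20 min, 0.809 at 1 h, 0.851 at 2 h and 0.964 at 10 h. For comparison, the controls at 10 min and 10 h were at 0.911.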

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

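The tests of scaling and of detection in this part were chosen after the result was seen; the test on genes with an unmoved main record was fixed before it. Where a gene ID stood on several rows, the row with the highest mean was its main record and the others were secondary records. Records below 1 FPKM took no part in the comparisons, and 6096 secondary records with a mean of 0.1 to 1 FPKM gave a signal above the controls. On the log2(FPKM + 0.1) scale their median heated-to-control ratio was 0.81 at 10 min, 0.81 at 20 min, 0.85 at 1 h and 0.32 at 2 h, and 0.00 at 10 h. At 10 min the authors' deposited table called 350 of them higher and 1 lower.

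Deeper sequencing or better detection in the heated libraries would raise both kinds of record alike if detection followed mean FPKM alone. The secondary records exceeded main records of matched mean FPKM by 0.71 at 10 min (bootstrap SE over records 0.03). Detection also depends on read counts, and thus on transcript length and depth, which were not known here, so this comparison cannot exclude it. Records above 0 FPKM numbered 39949 in the heated group and 37598 in the controls at 10 min. In the same comparison, 1 scaling factor per group would move both kinds alike, but the matched main records had a median of 0.09. Reads of heat-induced genes spilling into their own secondary records would leave genes with an unmoved main record alone. In 3329 secondary records whose main record moved by under 0.25 on the log2(FPKM + 1) scale, the median was 1.00 (SE 0.04). Such a main record could still gain more FPKM than the secondary records, whose median over all 6096 was 0.16 FPKM in controls and 0.44 FPKM after heat. This comparison therefore cannot exclude spilling. These SEs cover the choice of records, not replicates. What stays open, untested, is an effect of the heat itself on such transcripts, for example on unspliced or antisense RNA, and a difference in library preparation between heated and control samples, since the positions and strands of these records were not used here. Better detection in the heated libraries and spilling of reads from main records also stay open.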

How the results depend on the processing

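The other q thresholds for counts of calls, the 2-fold requirement, the count of gene IDs and the inclusion of mismatched records were chosen after seeing the data; the other settings were fixed before the data were examined. No paired analysis was possible because the columns carry no replicate. For the same reason the replicate block, the fit without trend, the fit of the contrast's libraries alone, leaving out each library, the estimated correlation and the self-contained list test (fry) were not run, and the GC and length relation had no sequence. Calls were the authors' and could not be refitted for another pseudocount, for rescaled groups or for rows summed per gene ID. Of 103 alternative values, 99 stayed within 1.5 times the reported count or, for the 4 named IDs, in the same direction, and 0 reversed. The 36 values for the named IDs were the only ones that could reverse, and they carry little weight. Another pseudocount cannot change their direction, and the rescaling factors lay between 0.951 and 1.048. With no filter on low values the calls at 10 min went from 884 to 1423, where more calls follow by construction from the added low records. The split turned from 362 higher and 522 lower to 882 and 541. The added calls include 350 higher and 1 lower among the secondary records of 0.1 to 1 FPKM, whose signal is unexplained. Calls at 10 h went from 1040 to 633 at a printed q of at most 0.01 and to 618 with at least a 2-fold ratio, each a stricter requirement. Records at least 2-fold different between control times went from 5621 to 3382 with a mean of at least 5 FPKM, with fewer records compared. With a pseudocount of 0.1 they went to 8184, which still lay within 1.5 times the reported count. The number of lists outside percentiles 2.5 to 97.5 was 5 at 10 min to 2 h and 1 at 10 h under both other settings run, and shared calls at adjacent times went from 4114 to 3021 at 0.01. Depth is unknown, and the smallest called ratio of FPKM values without a pseudocount, 1.55-fold, limits what the calls can show.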

Other observations

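The test on large rises in this part was chosen after the result was seen; the test on the heated shoots of the control-raised records was fixed before it, for the 20 min control group alone, and was widened to the 10 min group afterwards. The 864 records at least 2-fold higher in the 20 min controls than in the 10 min controls had a median in control shoots of 2.92 FPKM at 10 min, 10.87 at 20 min, 5.18 at 1 h, 3.75 at 2 h and 2.71 at 10 h, where the step from 10 to 20 min was fixed by the choice. In heated shoots the median was 4.50 FPKM at 10 min, 5.24 at 20 min, 12.02 at 1 h, 5.70 at 2 h and 2.44 at 10 h. The authors' deposited table called 300 of them higher after heat at 1 h, against 94.2 for independent lists. The heated shoots took no part in the choice. Chance values in the 10 or 20 min control group would leave them without a shift, if the chosen records otherwise behaved like matched ones. In heated shoots the log2 ratio of 1 h over 10 min exceeded that of records matched on mean FPKM by 0.96 (bootstrap SE over records 0.06). For 20 min over 10 min the difference from matched records was 0.22 (SE 0.02), and for 10 h over 10 min it was -0.72 (SE 0.07). The choice may favour variable records that also respond to heat, so these values cannot exclude chance in the controls. A second test fixed beforehand, the ratio of controls at 20 min over 1 h and 2 h, gave 1.07 above matched records and was set aside afterwards, because the records had been chosen on the 20 min value. Why these records were higher in heated shoots at 1 h was not tested, and an effect of heat, of handling or of time stays open. In the controls, the step from 10 to 20 min also went with the move from 22 °C to 30 °C.

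Of the records called higher at 10 h, 314 had no call at an earlier time in the authors' deposited table, with medians at 10 h of 50.23 FPKM against 25.54 FPKM. Another 133 were called lower at 1 h or 2 h and higher at 10 h in the authors' deposited table, with a median log2 ratio of -0.99 at 1 h and 0.91 at 10 h. The directions of these medians follow from the choice of records.

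Many large rises had no low q in the authors' deposited table. Among rises of at least 10-fold at 10 min to 2 h on the log2(FPKM + 0.1) scale, with at least 10 FPKM after heat, 45.1% of 494 were called where the control was below 1 FPKM and 86.8% of 794 where it was not, counting a record once per time. Control values near 0 may thus account for part of the missing calls. The 105 uncalled rises with a control of at least 1 FPKM, the highest at 13986.60 FPKM, could also reflect disagreement between replicates, which cannot be told apart from other causes because no value per replicate was analysed here.

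At 1 h, 36.0% of 325 records next in gene ID order to one of 166 records induced at least 20-fold to at least 100 FPKM had a log2 ratio of 1 or more, against 12.7% of all 21199 records so ordered, 19.4% at 2 positions and 17.3% at 3 positions. Of the neighbours on none of the 5 lists, a comparison fixed before its result was seen, the share was 32.9% (bootstrap SE over records 2.7). Induced records were not removed from the neighbours, so induced records that lie side by side count as each other's raised neighbour by construction.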
